A study of Mus musculus with 2 samples.

How the data were processed

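H3K27me3, the histone mark deposited by Polycomb repressive complex 2, was measured by chromatin immunoprecipitation and sequencing in the midbrain of healthy mouse embryos at embryonic day 14.5. The series holds 2 biological replicates. Replicate 1 was a pool of midbrains from 24 embryos with 2 technical replicates, and replicate 2 a pool from 34 embryos with 1 technical replicate, per the labels. Both pools held males and females, and fragments of 300 to 500 bp were selected. The samples form a single group, so no comparison between conditions was possible. The comparisons made here are between the replicates, between classes of genes and between regions of the genome.

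The deposited data analysed here are 4 lists of peaks in narrowPeak format on the mm10 assembly. Each replicate has its own list, made from that replicate's alignment and a control alignment, per the labels' accompanying file lists. A pooled list was made from the alignments and controls of both replicates. A list named replicated was derived from the pooled list and both replicates' own lists, by the same source. The aligner, the peak caller, their versions and the calling threshold are not given in the sources used here. For each peak the deposited lists give a score, the peak's overall enrichment as the narrowPeak format defines it, on a scale that is not stated. They also give the −log10 p and the −log10 q of each peak as the authors' peak caller computed them; the lowest −log10 p in any list was 2.03. These are the authors' values for the peak itself, and they were used only to describe, rank or filter peaks within a list. Read counts were not used here, so the sequencing depth of the replicates is unknown and no interval that needs depth is given. The number of peaks and the bases they cover stand in the report as the only measure of how much was called in each replicate. Peaks on chromosomes 1 to 19 and X were analysed.

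Every peak ended within the length of its chromosome in GRCm38, the assembly that mm10 names. Genes were taken from GENCODE release M21 on GRCm38. The 5′ end of a gene is the outermost annotated start of the gene on its strand. A gene was called marked if a peak of the list in question overlapped the 1000 bp on either side of its 5′ end by at least 1 bp. The covered share of a gene is the percentage of the 10 kb centred on its 5′ end that peaks cover, and it carries no information on signal height. The replicated list gives the main result throughout. Values of the separate replicate lists are given as mean ± SD with n = 2. Neighbouring genes can share a peak, as in the Hox clusters and at divergent promoters, so genes are not independent observations and p-values over genes describe these libraries.

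Agreement between the replicates was measured as the share of peaks overlapped by at least 1 bp and as shared bases over the union of bases. It was compared with 1000 circular shifts of replicate 1 along each chromosome, with runs of unknown bases left out, in a one-sided permutation test. Peak midpoints were assigned to promoters (within 1000 bp of any gene's 5′ end), exons, introns or intergenic sequence, in that order of precedence, and compared with 1000 circular shifts in a two-sided permutation test. The CpG ratio is the observed over expected number of CpG dinucleotides in the 1000 bp around the 5′ end; medians were compared by a two-sided permutation test with 100000 resamples. Before the data were examined, 19 gene lists with 502 entries and 483 distinct symbols were fixed; some genes stand in more than 1 list. All but 1 symbol (Nesp, in the imprinted list) matched a gene. Each list was tested against all other protein-coding genes by a two-sided Fisher's exact test, and against 10000 random lists matched on deciles of the CpG ratio. The list of midbrain regulators was compared with 4 other lists by Fisher's exact test on marked genes and by a two-sided permutation test with 100000 resamples on the mean covered share, after genes common to both lists were removed; bootstrap 95% confidence intervals used 10000 resamples. All p-values within a family of tests were adjusted by the Benjamini-Hochberg method. Domains were made by joining peaks no more than 3 kb apart.

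The genes named in the text follow a rule fixed before the data were examined. It took 14 chosen regulators and markers (Otx2, En1, En2, Lmx1a, Lmx1b, Foxa2, Pax3, Pax7, Gata3, Foxg1, Th, Tubb3, Sox2 and Ezh2), the 3 members of each list with the highest covered share and the 2 with the lowest, protein-coding genes whose 5′ end lay in the 10 longest domains, and marked members of the Polycomb and neurotransmitter lists. Ties were broken alphabetically. Any other gene is said to have been chosen after its values were seen.

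The procedures were tested on simulated data. Lists simulated with 30% and 60% of peaks shared gave 30.5% and 60.3%. Simulated lists of 30 genes with 40% of genes marked against a background of 10% were called in 94% of cases, and lists at the background share in 0.294%. The simulated peaks were placed at random and the simulated genes were marked independently of each other. Real peaks cluster and real genes can share a peak, so these rates need not hold for the lists tested here. The alternatives tried were stricter and looser overlap, narrower and wider windows, a −log10 q of at least 2, the upper 50% of peaks by −log10 p, the pooled list, each replicate's list alone, and other gaps for domains. Alternatives chosen after the data were seen were the replicated peaks overlapped by both replicates and the use of every annotated transcript start of a gene. Computations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.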

Results

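H3K27me3 was profiled by chromatin immunoprecipitation sequencing in mouse midbrain at embryonic day 14.5, in 2 pools of embryos that serve as biological replicates of a single group. Replicate 1 yielded 69398 peaks covering 30.4 Mb, or 1.19% of the genome, with a median width of 266 bp. Replicate 2 yielded 45996 peaks covering 15.5 Mb, or 0.606% of the genome, with a median width of 239 bp. The pooled list held 60454 peaks over 29.4 Mb. The replicated list held 26316 peaks over 20.8 Mb, with a median width of 465 bp and a longest peak of 25504 bp. The share of peaks with a −log10 q of at least 2 was 60.3% in replicate 1, 30.8% in replicate 2 and 83.4% in the replicated list. The sequencing depth behind these lists is unknown.

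The replicates were first compared with each other. Peaks of replicate 2 overlapped 27.6% of replicate 1 peaks (19181 of 69398), which was 21.3 times the mean of 1.30% (SD 0.156) in shifted genomes. Peaks of replicate 1 overlapped 56.9% of replicate 2 peaks (26159 of 45996), 27.2 times the shifted mean of 2.09% (SD 0.283). Shared bases made up 26.6% of the union, against 0.444% (SD 0.0932) after shifting. Each of these 3 values exceeded all 1000 shifts (one-sided permutation test, p = 0.001, the smallest these shifts can give). Replicate 1 contained 62.3% of the bases of replicate 2, while replicate 2 contained 31.8% of the bases of replicate 1.

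Peaks of the highest ranks were the most often shared. Among replicate 1 peaks, 10.8% of the lowest decile by −log10 p were overlapped by replicate 2, compared with 50.8% of the ninth decile and 86.8% of the highest. Among replicate 2 peaks the corresponding shares were 36.0%, 87.0% and 97.0%, with an uneven order in the lower deciles (41.5% in the second, 34.6% in the third, 47.8% in the fourth and 43.0% in the fifth). Peaks in the highest decile were also wider, with medians of 1042 bp in replicate 1 and 643 bp in replicate 2.

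**Figure D1:**
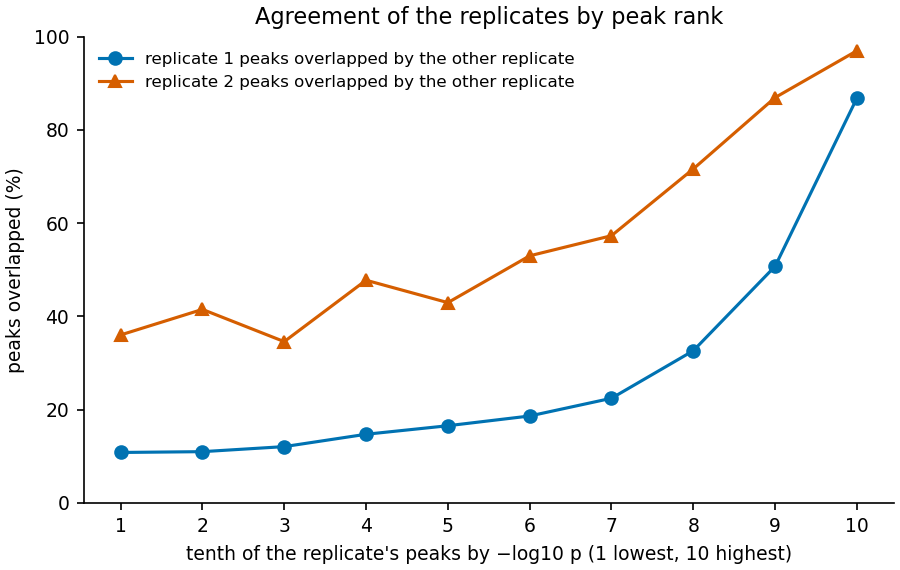
Share of each replicate's peaks overlapped by at least 1 bp by a peak of the other replicate (y axis, percent), by decile of the replicate's own peaks ranked on −log10 p (x axis, 1 lowest and 10 highest). Circles are replicate 1 and triangles replicate 2; the share reached 86.8% and 97.0% in the highest decile. Peaks tied on −log10 p were divided between deciles by genome position.

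The replicated list was a subset of the pooled list, with all 26316 intervals unchanged. It included all 16644 pooled peaks that a peak of each replicate overlapped by at least 50% of either of the overlapping peaks, and these made up 63.2% of it. By 1 bp of overlap, 94.1% of replicated peaks met a replicate 1 peak, 69.0% met a replicate 2 peak and 64.4% met both. The peaks that met both held 82.6% of the bases in the list. The remaining peaks were in the replicated list without overlapping a peak in each replicate's own list.

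H3K27me3 peaks were concentrated at gene starts. Of the replicated peaks, 15.7% had their midpoint within 1000 bp of an annotated 5′ end, against 3.92% (SD 0.196) in shifted genomes, a 4.00-fold excess. Exons held 8.03% of midpoints, a 2.01-fold excess over the shifted mean of 3.99%. Intergenic sequence held 36.4% of midpoints, 0.717 times the shifted mean of 50.8%. These 3 classes each passed the two-sided permutation test (adjusted p = 0.00266, from the smallest p the shifts can give). Introns held 39.8% of midpoints against 41.3% after shifting and did not pass (permutation test, adjusted p = 0.226). The promoter excess was 2.83-fold in replicate 1 and 3.46-fold in replicate 2.

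Of 21755 protein-coding genes, 2979 (13.7%) had a marked 5′ end in the replicated list. Replicate 1 marked 4080 genes and replicate 2 marked 2949, a mean of 3514.5 ± 800 (SD, n = 2), and 2614 genes were marked in both replicates. Of those 2614 genes, 95.1% were marked in the replicated list as well. When at least 50% of the window had to be covered, the number of marked genes fell to 1522.

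Marked 5′ ends were richer in CpG dinucleotides than unmarked ones. The median CpG ratio was 0.637 at the 2979 marked 5′ ends and 0.519 at the 18776 unmarked ones, a difference of 0.118 (two-sided permutation test, p = 1e-05, the smallest the resamples can give). The relation was not a steady rise. The marked share was 0.966% in the lowest decile of the CpG ratio, reached 27.2% in the fifth decile (ratios of 0.406 to 0.558) and declined to 10.4% in the highest decile. Both replicates had their maximum in the same decile, at 36.8% in replicate 1 and 26.4% in replicate 2, with a mean of 31.6% ± 7.35 (SD, n = 2).

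**Figure D2:**
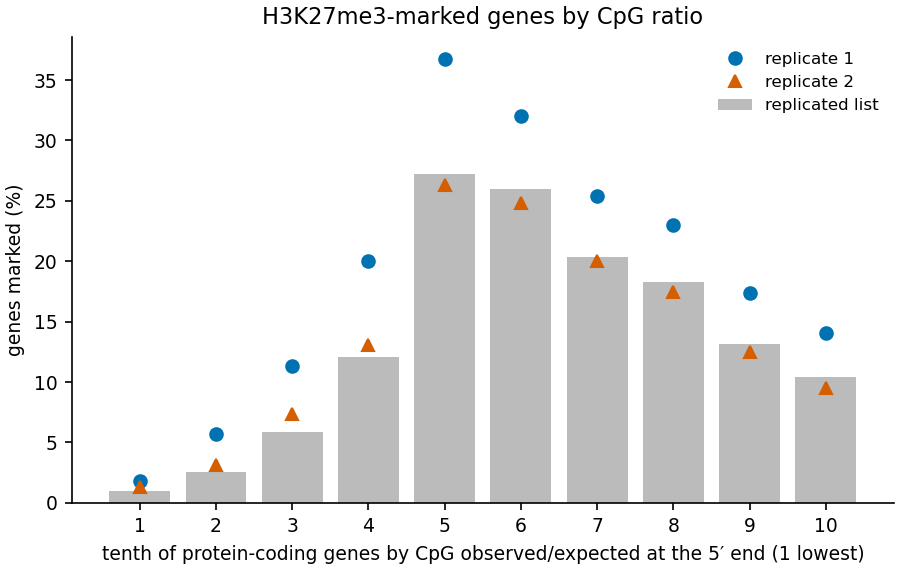
Share of protein-coding genes with a marked 5′ end (y axis, percent) by decile of the CpG observed over expected ratio around the 5′ end (x axis, 1 lowest and 10 highest). Bars show the replicated list, circles replicate 1 and triangles replicate 2; all have their maximum in decile 5, at 27.2% for the replicated list.

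Genes that control patterning and cell fate carried the mark far more often than other genes. In 13 of the 19 lists fixed in advance the marked share was higher than among all other protein-coding genes, and in 1 list it was lower (two-sided Fisher's exact test, adjusted p under 0.05). The same numbers of lists passed against random lists matched on the CpG ratio. Covered shares below are of the replicated list unless a replicate is named. Replicate 2 gave a lower share than replicate 1 at all 116 genes of the naming rule with a replicated covered share above 0, and differed from the replicated list by over 1.5 times at 36 of them, against 7 for replicate 1. All 39 Hox genes, which specify position along the body axis behind the midbrain, were marked (adjusted exact p = 3.23e-33), in each replicate as well as in the replicated list. All 28 regulators of hindbrain and spinal cord were marked (adjusted exact p = 3.77e-24), as were 27 of 30 forebrain regulators (90%, adjusted exact p = 3.70e-20). Replicate 1 marked 28 of the hindbrain and spinal regulators and replicate 2 marked 26, and each replicate marked 27 of the forebrain regulators. Among the hindbrain and spinal regulators the highest covered shares were at Mnx1 with 98.9% (chromosome 5, 29473034–29478470), Skor1 with 98.1% and Evx1 with 96.0%. The lowest in that list, Irx3 and Lhx3, had 25.2% and 53.1%, and Irx3 was unmarked in replicate 2. Among forebrain regulators, the 10 kb around Six3 (chromosome 17, 85613608–85629302) were covered completely, with a replicate mean of 94.6% ± 7.70 (SD, n = 2). Gsx2 and Dlx1, homeobox genes of the ventral forebrain, followed with 98.1% and 97.7%. Foxg1, the forkhead factor of the telencephalon (chromosome 12, 49382660–49386861), had 79.5% covered, with 65.1% ± 14.2 (SD, n = 2) over the replicates. Neurod6 and Hesx1 were unmarked, with 2.00% and 0% covered.

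Regulators of tissues outside the nervous system were also marked more often than other protein-coding genes. The mark was present at 31 of 34 mesoderm regulators (91.2%, adjusted exact p = 2.77e-23), 19 of 22 endoderm regulators (86.4%, adjusted exact p = 9.01e-14) and 20 of 22 regulators of surface ectoderm and neural crest (90.9%, adjusted exact p = 2.42e-15). Covered shares reached 98.8% at Pax9, 98.1% at Pax1 and 98.0% at Foxf1 among mesoderm genes. They reached 98.9% at Foxa2 and 98.4% at Cdx2 in the endoderm list, and 98.8% at Msx2 and 97.8% at Tfap2a in the surface ectoderm and neural crest list. Of these lists, 7 mesoderm, 6 endoderm and 5 surface ectoderm and neural crest genes also stand in other lists. Foxa1 and Foxa2 of the endoderm list are also midbrain regulators, and Mnx1 is also a hindbrain and spinal regulator. The results for these 3 lists are therefore not independent of those for the other lists. The muscle determination factors Myf5 and Myf6, neighbours on chromosome 10, had 0% covered in both replicates. Hnf4a, Isx, Foxn1 and Trp63 were also at 0% in the replicated list. Of 42 genes for secreted signalling ligands, 37 were marked (88.1%, adjusted exact p = 3.69e-26). Wnt10b and Wnt1, adjacent on chromosome 15, had 94.6% and 87.5% covered, and Ihh had 88.0%. Bmp5 and Fgf20 had none of the 10 kb covered, although an alternative start of Fgf20 was marked.

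Regulators of the midbrain itself were marked in 30 of 35 cases (85.7%, adjusted exact p = 6.70e-21), with 34 marked in replicate 1 and 28 in replicate 2. Each library was made from pooled midbrains, so a peak does not show which cells carried the mark. It may come from cells that do not use the gene. The covered shares of these regulators ranged widely. Foxa2, a floor plate and dopaminergic progenitor factor (chromosome 2, 148042877–148046969), had 98.9% covered and a replicate mean of 84.6% ± 20.4 (SD, n = 2). Foxa1 and Nkx2-2 had 96.0% and 93.7% covered. The dopaminergic lineage factors Lmx1b and Lmx1a had 90.3% and 73.5% covered, with replicate means of 73.9% ± 20.7 and 52.0% ± 29.6 (SD, n = 2). Gata3 of the GABAergic lineage had 77.2% covered, with 84.2% in replicate 1 and 46.3% in replicate 2. The dorsal regulator Pax7 had 64.7%, with 69.9% in replicate 1 and 26.0% in replicate 2, where it was unmarked. Pax3 had 46.3%, with 40.7% ± 8.97 (SD, n = 2) over the replicates. En1 had 53.6%, with 62.3% in replicate 1 and 25.4% in replicate 2. Otx2, which marks forebrain and midbrain identity (chromosome 14, 48657677–48673819), was marked but had 17.9% covered, with 16.0% ± 17 (SD, n = 2) over the replicates. En2 (chromosome 5, 28165694–28172166) had 25.9% covered and no replicated peak within 1000 bp of its 5′ end, although replicate 1 alone marked it. Tal2 and Tcf7l2 were unmarked in the replicated list, with 3.90% and 0% covered, although replicate 1 alone marked both, with 11.8% and 5.38% covered. A different annotated start of Tcf7l2 was marked. The other unmarked midbrain regulators were Ascl1 and Meis2, named after their values were seen, and replicate 1 marked Meis2.

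The covered share of midbrain regulators was then set against 4 lists, with shared genes removed. The 35 midbrain regulators averaged 64.6% (SD 30.5 over genes) and the 39 Hox genes 97.3% (SD 3.11), a difference of −32.7 percentage points (95% CI −42.8 to −23.0, permutation test, adjusted p = 4e-05, from the smallest p the resamples can give). The Hox genes lie in 4 clusters and many of their windows overlap. The SD, interval and p of this comparison count shared bases as independent and so overstate its precision. Against 27 hindbrain and spinal regulators at 80.9% (SD 16.8), the 34 remaining midbrain regulators averaged 63.8%, a difference of −17.1 points (95% CI −28.9 to −4.98, permutation test, adjusted p = 0.0218). The difference from 30 forebrain regulators at 74.95% was −10.4 points (95% CI −24.1 to 3.57) and did not pass (permutation test, adjusted p = 0.207). The difference from 34 mesoderm regulators at 68.5% was −3.91 points (95% CI −18.4 to 10.8) and did not pass either (permutation test, adjusted p = 0.608). All 4 differences in covered share kept their sign in each replicate's own list. The difference in the share of marked genes passed against none of the 4 lists (Fisher's exact test, adjusted p of 0.0806 for Hox, 0.121 for hindbrain and spinal, and 0.716 for forebrain and for mesoderm). For Hox that call depended on the peaks used, since replicate 2 alone gave an exact adjusted p = 0.0149, within a range of 0.000399 to 0.819 over its alternatives.

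Lists of neurotransmitter genes, of genes expressed in neural progenitors or neurons, and of housekeeping genes were tested against all other protein-coding genes in the same way. Of 20 genes that define a neurotransmitter identity, 12 were marked (60%, adjusted exact p = 3.88e-06). The highest covered shares were 94.6% at Slc6a5, the glycine transporter, 78.9% at Slc18a3 and 78.4% at Slc32a1. Chat had 68.4%, Gad2 58.9%, Slc17a7 58.8%, Slc6a4 44.3%, Pnmt 36.9%, Slc6a2 33.1%, Slc18a2 32.0% and Slc5a7 9.03%. The dopamine transporter gene Slc6a3 had 28.9% covered, with 28.4% ± 12.3 (SD, n = 2) over the replicates. Th, which encodes the rate-limiting enzyme of dopamine synthesis (chromosome 7, 142892752–142931128), had 0% covered in both replicates, and neither of its 2 annotated starts was marked. Of 30 genes widely expressed in neural cells, 6 were marked (20%, adjusted exact p = 0.324, not passed). Within that list Hes1 had 61.2%, Nefl 41.4% and Sox2 14.4% covered, while the neuronal tubulin gene Tubb3 and the neuroblast gene Dcx had 0%. None of 30 housekeeping genes was marked (0%, against 13.7% of other genes, adjusted exact p = 0.0380). That call was lost under 5 of 10 alternatives, among them replicate 2 alone, where 1 of the 30 genes was marked (adjusted exact p = 0.144, within a range of 0.00898 to 0.339 over its alternatives).

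Markers of other cell types in or around the embryonic brain gave a mixed picture. The oligodendrocyte lineage list was marked in 8 of 15 cases (53.3%, adjusted exact p = 0.000507), with 98.0% covered at Olig2, 93.7% at Nkx2-2 and 87.9% at Olig1, and 0% at Bcas1 and Gpr17. Olig2 had 98.6% covered in replicate 1 and 49.4% in replicate 2. The endothelial and mural list was marked in 9 of 16 cases (56.3%, adjusted exact p = 0.000133), led by Flt1 with 80.8% and Esam with 64.3%, while Cdh5 had 0%. The list for meningeal mesenchyme was marked in 10 of 15 cases (66.7%, adjusted exact p = 6.74e-06), with 91.1% at Alx4, 85.4% at Foxd1 and 83.5% at Twist1 against 0% at Col3a1. Of its genes, 5 also stand in the lists of mesoderm or of surface ectoderm and neural crest regulators, and all 5 were marked. The oligodendrocyte list shares 2 genes, both marked, with the lists of regulators. These calls are therefore not independent of the results for regulators. Microglial markers were marked in 4 of 15 cases (26.7%, adjusted exact p = 0.176, not passed), among them C1qc with 30.9% and Irf8 with 25.5% covered. C1qa had 32.6% covered but was unmarked. Replicate 1 marked 6 of the 15, C1qa among them, and replicate 2 marked 2, without C1qa and C1qc. Among germline genes 2 of 27 were marked (7.41%, adjusted exact p = 0.604), and both, Dmc1 and Spo11, had under 15% covered. Replicate 1 marked 6 of these 27 genes, and Spo11 was unmarked in replicate 2. Of 26 terminal genes of liver and blood, 1 was marked (3.85%, adjusted exact p = 0.293), the erythroid factor Klf1, which was unmarked in replicate 2. Imprinted genes were marked in 9 of 24 cases (37.5%, adjusted exact p = 0.00457), with 80.8% at Grb10, 73.1% at Dlk1 and 70.7% at Ascl2, and 0% at H19 and Kcnq1ot1. Over the 4 annotated starts of Grb10 the covered share ran from 0% to 93.2%. Genes for Polycomb subunits were marked in 4 of 31 cases (12.9%, adjusted exact p = 1), with 7 marked in replicate 1 and 4 in replicate 2. The marked genes were Epop with 58.3% covered, Cbx4 with 52.1%, Pcgf5 with 32.8% and Phf19 with 20.3%. Pcgf5 also has 4 annotated starts, with covered shares from 0% to 32.8%. Cbx8 had 72.4% of its 10 kb covered without a replicated peak within 1000 bp of the 5′ end. Replicate 1 marked it, with 75.9% covered, and replicate 2 did not, with 44.9%. Ezh2, which encodes the methyltransferase itself (chromosome 6, 47530139–47595341), had 0% covered in both replicates.

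**Figure D3:**
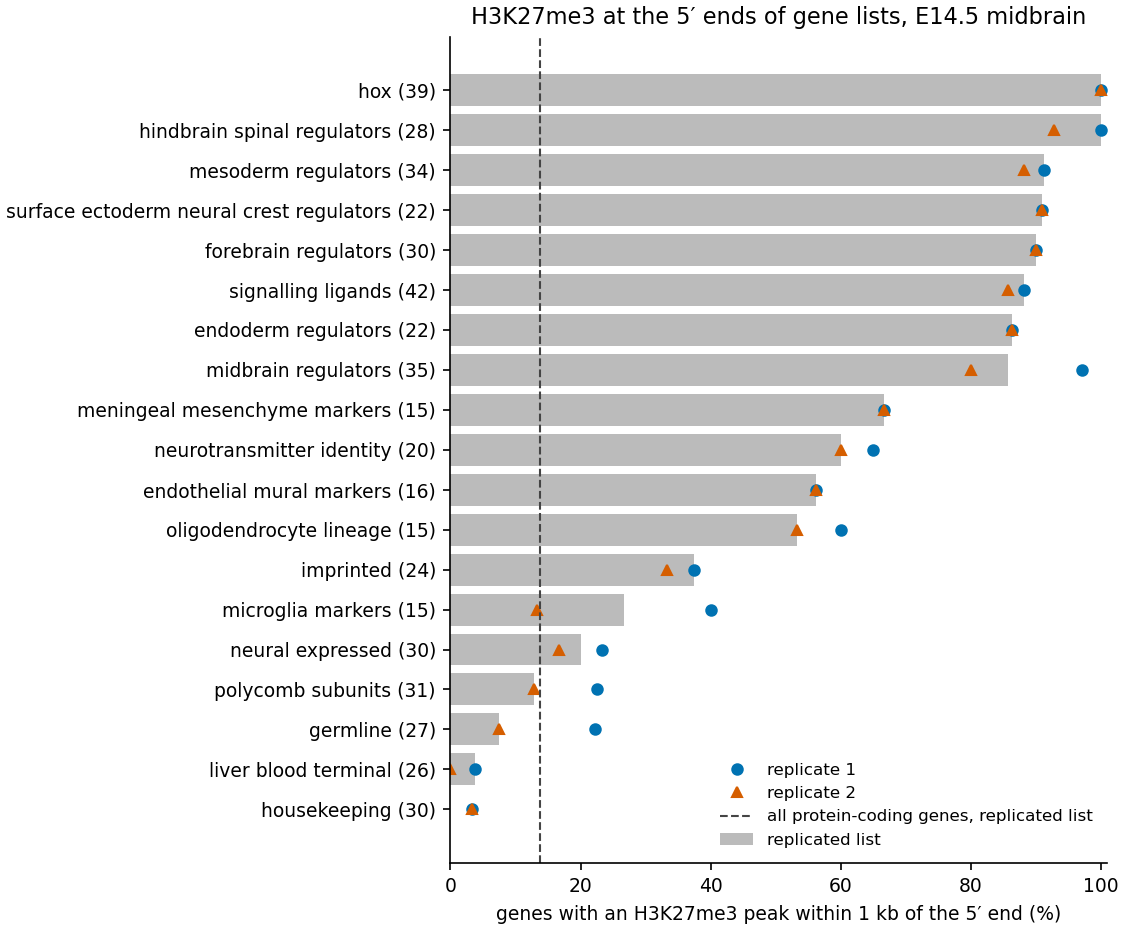
Share of each gene list with a peak within 1000 bp of the 5′ end (x axis, percent), with the number of genes per list in brackets. Bars show the replicated list, circles replicate 1 and triangles replicate 2. The dashed line is the 13.7% of all protein-coding genes marked in the replicated list. The bars of developmental regulators lie at 85.7% or more and that of housekeeping genes at 0%. Replicate 2 marked 28 of 35 midbrain regulators, and each replicate marked 1 of 30 housekeeping genes.

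H3K27me3 peaks formed long domains at a small number of loci. Joining replicated peaks no more than 3 kb apart gave 10077 domains with a median length of 820 bp. Of these, 640 were longer than 10 kb and together held 45.4% of the covered bases, and 20 were longer than 50 kb. The counts depended on the list, with 1186 over 10 kb and 48 over 50 kb in replicate 1, 571 and 13 in replicate 2, and 1143 and 56 in the pooled list. The 4 longest lay over the Hox clusters. They spanned 174 kb at the Hoxc genes (chromosome 15, 102897568–103071935), 156 kb at Hoxa (chromosome 6, 52144978–52301142), 131 kb at Hoxb without Hoxb13 (chromosome 11, 96245973–96377457) and 127 kb at Hoxd with Evx2 (chromosome 2, 74642288–74768976). In replicate 1 alone and in the pooled list, 3 of the 4 longest domains held Hox genes, and with a joining gap of 10 kb 2 did. The next longest was a 96.9 kb domain within the body of Rnf220 (chromosome 4, 117342453–117439310) that contained no annotated 5′ end. A 90.4 kb domain contained the 5′ end of Pax3 (chromosome 1, 78131295–78221743). It was followed by 77.0 kb at Scn5a, which encodes a voltage-gated sodium channel (chromosome 9, 119512481–119589445), and 72.2 kb at Fezf2 (chromosome 14, 12333276–12405523). A 75.3 kb domain on chromosome 7 (49650776–49726119) overlapped no protein-coding gene. The longest on the X chromosome, 63.6 kb, lay within Iqsec2 (152164695–152228329). Rnf220, Iqsec2 and Hoxb13 are named for the position of a region and were chosen after its values were seen. Peaks covered 93.9% of the Hoxc domain but 60.5% of the Rnf220 domain and 43.2% of the Iqsec2 domain. Replicate coverage of the Rnf220 domain was 45.6% ± 24.7 (SD, n = 2), with 63.0% in replicate 1 and 28.1% in replicate 2. For the Iqsec2 domain it was 49.5% in replicate 1 and 18.9% in replicate 2.

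Replicated peaks covered nearly all of the Hoxa, Hoxc and Hoxd clusters and less of Hoxb. From the first to the last Hox gene, replicated peaks covered 96.7% of the 105 kb Hoxa cluster, 98.1% of the 116 kb Hoxc cluster and 96.8% of the 96.8 kb Hoxd cluster. The 174 kb Hoxb cluster was covered to 78.3%, which left 37.7 kb uncovered. Of this, 85.2% lay in 5 stretches of at least 1 kb between Hoxb13 and Hoxb9. The longest was 18288 bp (chromosome 11, 96216082–96234369), followed by 5580 bp (96240393–96245972) and 5449 bp (96210290–96215738), whereas the longest in the other clusters was 630 bp. Replicate means were 90.01% ± 9.02 for Hoxa, 72.4% ± 9.997 for Hoxb, 91.8% ± 9.18 for Hoxc and 87.7% ± 12.1 for Hoxd (SD, n = 2). Hoxb was the least covered cluster in each replicate, at 79.5% in replicate 1 and 65.4% in replicate 2.

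**Figure D4:**
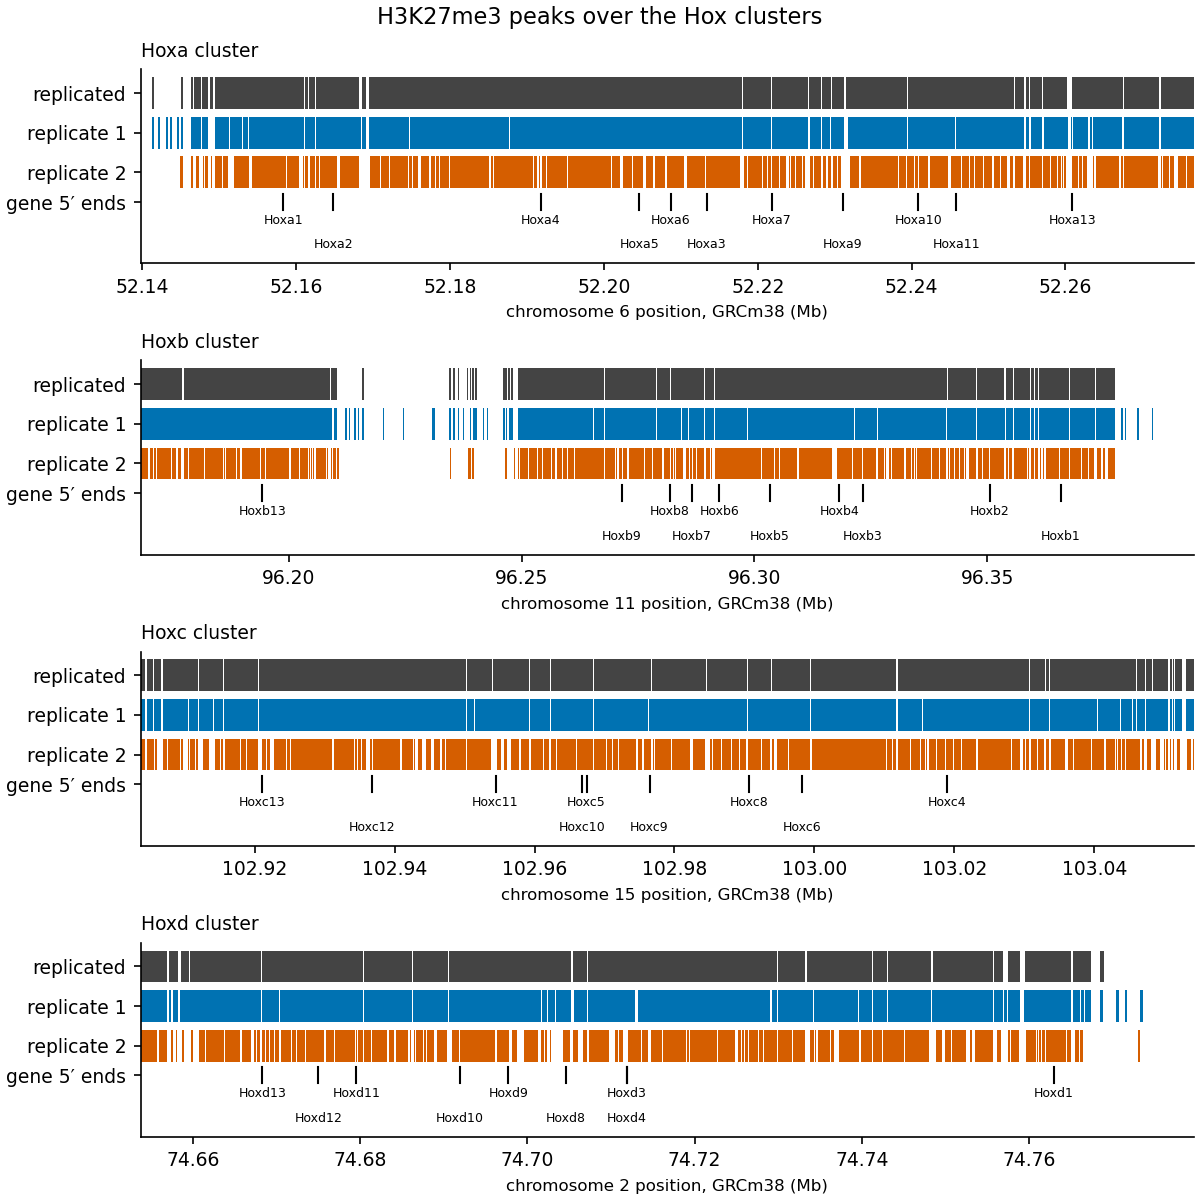
Peaks of the replicated list and of each replicate (bars) over the Hoxa, Hoxb, Hoxc and Hoxd clusters on GRCm38 (x axis, chromosome position in Mb), with the 5′ ends of the Hox genes as ticks. Peaks cover 96.7%, 78.3%, 98.1% and 96.8% of the clusters in the replicated list, and the 5 uncovered stretches of at least 1 kb lie between Hoxb13 and Hoxb9.

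Coverage differed between chromosomes. On average 0.851% of an autosome (SD 0.315 over 19 autosomes) was covered by replicated peaks, from 0.457% of chromosome 3 to 1.72% of chromosome 19. Chromosome 19 was the most covered and chromosome 3 the least in each replicate as well. The X chromosome held 13.8 peaks per Mb, 1.35 times the autosome mean of 10.2, but its peaks had a median width of 345 bp against 483 bp on autosomes, and 0.562% of it was covered. Both X values lay within the range of the autosomes. The replicates differed on X, with 40.6 peaks per Mb in replicate 1 (1.52 times its autosome mean) and 18.3 in replicate 2 (0.999 times). The covered share of X relative to the autosome mean was 0.661 in the replicated list, 0.991 in replicate 1 and 0.721 in replicate 2.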

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

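Of 341 recomputed values for 44 results, 300 stayed the same. Tested results stayed the same if they kept their direction and their side of the threshold. Counts did so within 1.5 times the main count in either direction. Other values did so if they differed from the main value by less than the SD over both replicates. The peaks overlapped by both replicates and the use of every transcript start were alternatives chosen after the data were seen. By these rules a −log10 q of at least 2 changed none of the 44 results. The SD rule is loose where the replicates differ. For peaks per Mb on X over the autosome mean, the filter took the replicated list from 1.35 to 1.15, which still counted as the same. Replicate agreement had no opposite direction, so it could change only by failing its test. The 13 lists with more marked genes passed under all 10 of their alternatives, as did the differences in covered share between midbrain and hindbrain and spinal regulators (−18.8 to −12.5 points, adjusted p of 0.0110 to 0.0480) and between midbrain and Hox genes (−40.2 to −29.5 points) under their 6. For the values below the cause was not tested.

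Requiring at least 50% of the window to be covered gave 1522 marked genes, neural genes at 6.67% and microglial markers at 0% (both now below other genes), housekeeping genes at 0% without passing, and a midbrain minus Hox difference in marked share of −31.4 points that passed. The upper 50% of peaks gave housekeeping at 0% without passing, Polycomb subunits at 12.9% (above other genes) and midbrain minus Hox at −20 points, which passed. Peaks overlapped by both replicates gave housekeeping at 0% without passing, Polycomb subunits at 12.9% (above), midbrain minus Hox at −17.1 points, which passed, and a covered share of X of 0.448 times the autosomes. Polycomb subunits also changed side, without passing, with 2.5 kb windows (29.0%) and every transcript start (19.4%). With promoters of 2.5 kb, introns held 31.2% of midpoints and passed as fewer than shifted. The pooled list gave introns at 41.4% (above shifted, not passed), housekeeping genes at 6.67% without passing, Polycomb subunits at 22.6% (above), midbrain minus forebrain at 7.14 points and minus mesoderm at 3.03 points in marked share, 20856 domains, 1143 of them over 10 kb, and a covered share of X of 0.941 times the autosomes. Gaps of 1 kb and 10 kb gave 376 and 1201 domains over 10 kb.

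With each replicate's list alone, introns held 40.9% to 41.2%, housekeeping genes were marked at 3.33% in each, germline genes at 7.41% to 22.2%, microglial markers at 13.3% to 40% and Polycomb subunits at 12.9% to 22.6%. Differences in marked share ranged from −10.0 to 7.14 points for forebrain, −8.24 to 5.97 for mesoderm and −20 to −2.86 for Hox. Domains numbered 20456 to 27296, with 571 to 1186 over 10 kb. Coverage was 83.6% to 96.4% of Hoxa, 65.4% to 79.5% of Hoxb, 85.3% to 98.3% of Hoxc and 79.1% to 96.2% of Hoxd, and X was covered at 0.721 to 0.991 times the autosomes. No paired analysis was possible because the series holds a single group. Unknown depth limits any statement on regions without a peak.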

Other observations

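The tests of symbol roots, of replicate 1's own domains and of the ribosomal RNA peaks were chosen after the result was seen, and so were the saturation limit of the domain test, the bootstrap interval and the use of replicate 2 as a control in the tests of the X chromosome. Protein-coding genes were grouped by the letters that open their symbols, and the 279 roots with at least 10 members were each compared with all other protein-coding genes (two-sided Fisher's exact test with Benjamini-Hochberg adjustment). The mark was more frequent in 24 roots and less frequent in 10, of which 15 and 7 also passed against random lists matched on the CpG ratio. Outside the Hox genes, 18 of 19 Wnt genes and 13 of 14 Nkx genes were marked (adjusted exact p = 4.22e-13 and 3.97e-09). All 19 Wnt genes stand in the list of signalling ligands, so their result repeats part of that one. Some of the Nkx genes also stand in the lists above. Classes that the lists covered little were also marked more often, among them 22 of 45 collagen genes (Col, adjusted exact p = 5.53e-07) and 11 of 19 Adamts metalloproteinase genes (adjusted exact p = 0.000206). Of integrin alpha subunits with a number after Itga, 8 of 12 were marked (adjusted exact p = 0.000668). Alpha subunits with a further letter after Itga fell outside this root. Receptor and channel genes included 9 of 14 serotonin receptor genes (Htr, adjusted exact p = 0.000348), 9 of 14 Kcnk and 9 of 15 Kcnj potassium channel genes (adjusted exact p = 0.000348 and 0.000668). Collagen genes numbered 29 marked in replicate 1 and 23 in replicate 2, and Adamts genes 13 and 8.

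Peaks were scarce at other large families. In the replicated list, none of 1134 olfactory receptor genes (Olfr, adjusted exact p = 9.35e-73) and none of 330 vomeronasal receptor genes (Vmn, adjusted exact p = 1.22e-19) was marked, against 31.9 and 6.88 in lists matched on the CpG ratio (adjusted permutation p = 0.00399 and 0.0266). Replicate 1 marked 4 olfactory receptor genes and replicate 2 marked 2. Zinc finger genes named Zfp were marked in 13 of 394 cases (3.30%, adjusted exact p = 2.74e-10), against 73.9 in matched lists, with 23 marked in replicate 1 and 13 in replicate 2. None of 67 histone genes (Hist, adjusted exact p = 0.00166) and none of 54 genes of the large ribosomal subunit (Rpl, adjusted exact p = 0.00753) was marked in the replicated list, against 9.24 and 8.91 in matched lists. Each replicate marked 2 Rpl genes. Olfactory receptor and histone genes lie in tandem arrays, so their members are not independent. How well reads align to families of similar gene copies was not examined, and the CpG matching takes no account of it. An absence of peaks at these families is therefore not shown to be an absence of the mark.

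Replicate 2 gave fewer and narrower peaks than replicate 1, although its pool held more embryos. Background calls placed without regard to gene starts are argued against as the whole of replicate 1's excess. No replicate 2 peak overlapped 50217 replicate 1 peaks. Of these, 8.51% lay within 1000 bp of a 5′ end, against 3.89% (SD 0.150) after shifting. The 19837 replicate 2 peaks without a replicate 1 overlap were also in excess there, at 6.34% against 3.90% (SD 0.168). Background calls that gather at gene starts would give such an excess too, so they stay open. Whether the unmatched peaks of either list carry the mark was not tested. A less sensitive replicate 2 library stays open: 99.2% of the 1186 domains over 10 kb made from replicate 1's own peaks held a replicate 2 peak, but a single peak in a long domain sufficed, so this measure is saturated and decides nothing. Differences in read number, in the number of technical replicates and between the embryo pools stay open, and no biological explanation was tested.

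The X chromosome held 1.52 times the autosome mean of peaks per Mb in replicate 1 and 0.999 times in replicate 2. With a −log10 q of at least 2, the replicate 1 ratio was 1.33, but its 95% bootstrap interval over bins of 1 Mb ran from 0.890 to 1.83, so peaks near the calling threshold can be neither excluded nor shown as the cause. The same filter took the replicate 2 ratio from 0.999 to 0.502 and that of the replicated list from 1.35 to 1.15, so it did not bring the replicates closer. The inactive X of female embryos is a candidate explanation that would place peaks away from gene starts: X peaks of replicate 1 lay near 5′ ends 1.72 times as often as shifted ones, below each autosome (2.08 to 4.12 times). Replicate 2 had the same order, 2.04 times against 2.62 to 5.002, without an excess of peaks, so this test does not separate the explanation from others. Sexes were pooled in both replicates, so the inactive X does not by itself account for a difference between them. The share of females in each pool is not known here, and the explanation stays open.

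The 2 replicated peaks with the highest −log10 p, 146 and 119, lay on chromosome 17 (39843011–39846804 and 39847850–39848929) over an annotated ribosomal RNA gene copy. Their enrichment scores of 3.61 and 3.07 were ordinary, and the higher of these stood at the 53.4th percentile of the list, whereas 6 of the 10 peaks of highest −log10 p were in its top 1%. Reads shared between copies of the ribosomal RNA repeat may account for such a small p at a moderate enrichment. Among the 100 peaks of highest −log10 p, 3 had a score below the 75th percentile, and the other was a 498 bp peak on chromosome 11 (109011587–109012084) that overlapped no GENCODE gene. Enrichment of the mark on ribosomal RNA genes stays open and was not tested. Klf14, named after its value was seen, held the fourth peak by −log10 p, and its score of 16.1 was the highest in the list.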
